A study of Mus musculus with 10 samples.

How the data were processed

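RNA from glomeruli of 10 mice was labelled with biotin and hybridised to Affymetrix arrays, 1 array per mouse, with 6 mice given LPS and 4 given PBS, per the labels. The deposited table holds log2 expression values for 45101 probe sets on each array. The authors computed them with GCRMA 2.6.0 in R 2.4.1, per the submitters' processing notes; GCRMA corrects the background, normalizes between arrays and summarizes the probes of a probe set on the log2 scale, and the settings used are not given in the sources used here. That the values are log2 was read from their range and from the near-equal distributions on all arrays. Normalization between arrays sets the distributions of the arrays equal, so a change shared by most genes would not show in these values. GCRMA also draws dim probe sets to a common low level, which makes folds from that level uncertain.

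Genes were named from the array's annotation: 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none, besides 64 control probe sets, which were left out of the fits. No gene was named from a probe set with several symbols. A probe set entered when its log2 value was above 4 on at least 4 of the 10 arrays, which 19650 did. Each gene was represented by the 1 probe set with the highest mean over all 10 arrays, which gave 10518 genes of the 18193 with a probe set. Of the changed genes, 2380 had more than 1 probe set past the filter, and for 171 of them another probe set passed the threshold in the opposite direction.

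Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05; a size threshold of 2-fold was counted beside it. Where every array of a group was at or under a log2 value of 4, the fold was given as a lower bound, computed from the mean of the other group against 4.

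Before the data were examined, 34 gene lists for glomerular, tubular and blood cell types and for endotoxin responses were fixed from general knowledge, together with the test, the filter, the alternatives and the rule for named genes. Of 560 list entries 508 were matched to a symbol of the annotation, and the other 52 were not analysed here. After the filter 418 different genes were measured, and 12 of them stood in more than 1 list. Genes dim on all arrays of a group could pass the filter only through the other group, and dim genes without a change were left out. Counts and medians over measured members lean towards changed genes for that reason. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01 and adjusted over 33 lists, with camera at an estimated correlation and fry as alternatives. Camera compares a list with all other genes, and fry asks whether the genes of a list moved one way. The genes named were the 10 highest and 10 lowest log2 changes among changed genes with separated arrays, up to 3 members of each list in the direction of its median and 1 in the other, and a fixed set of podocyte, endotoxin response and vascular genes; not every gene that the rule allows was named. Another 11 lists were written after the main results were seen.

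The test was tried on simulated data with the levels and spread of the 10518 genes. It recovered 61 of 100 genes changed by 0.5 and 90 of 100 changed by 1 on the log2 scale, none with the wrong sign, with 12 false calls, and made 0 calls without any change. Both simulated changed lists were recovered and 0 of 100 unchanged lists were called. The simulated genes varied independently of each other. The simulation therefore does not show how often camera at the preset correlation calls lists of correlated genes. Only 100 genes were changed at each size, while 5183 of 10518 genes were called in the data. The adjustment of p-values depends on that share, so the simulated recovery and false calls do not carry over to the data.

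Alternatives covered the filter on dim probe sets, quantile normalization, median centring, a floor at 4, the mean of a gene's probe sets, every probe set on its own, eBayes without trend or robust, array weights, the replicate number as a block, and leaving out each array. Counts of list members without LPS replicate 4 were added after the data were seen. Single values were compared with exact permutation tests over all 210 splits. Scan dates and other batch information were not given in the sources used here, so batch and group could not be compared. The control probe sets gave a difference between the 3-prime and 5-prime signals of Gapdh of -0.32 ± 0.08 (SD, n = 6) after LPS and -0.30 ± 0.07 (SD, n = 4) after PBS (exact two-sided permutation p = 0.624), and of beta-actin of 0.87 ± 0.09 and 0.80 ± 0.08 (exact two-sided permutation p = 0.243).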

Results

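Total RNA from kidney glomeruli, the filtering units of the kidney, was measured on 3-prime expression arrays in 10 female C57BL/6 mice aged 9 weeks. A single intraperitoneal injection of lipopolysaccharide (LPS), the bacterial endotoxin used here to induce proteinuria, had been given to 6 mice, and 4 mice had received phosphate-buffered saline (PBS). Glomeruli were taken 24 hours after the injection, and each array held the RNA of 1 mouse, which the labels call biological replicates. The comparison addresses which glomerular transcripts differ between mice given endotoxin and mice given buffer. Values are log2 expression values as deposited, between 1.03 and 15.71, and the array medians lay between 3.21 and 3.30. Between 43.0% and 43.6% of the probe sets lay above a log2 value of 4 on each array. The number of arrays limits the precision of every value below.

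One day after endotoxin most measured acute phase, chemokine, leukocyte adhesion and interferon-stimulated transcripts were higher in the glomerular preparation, and most measured podocyte and mesangial markers were lower. With an estimated correlation between genes the acute phase list kept its call (camera adjusted p = 0.0354). The chemokine (0.0745), adhesion (0.0971), interferon (0.0745), podocyte (0.236) and mesangial (0.233) lists did not. Lcn2, which encodes an iron-binding acute phase protein, was at 14.79 ± 0.28 (SD, n = 6) after LPS and at 3.01 ± 0.53 (SD, n = 4) after PBS, at least 1774-fold higher. Nphs1, which encodes nephrin of the podocyte slit diaphragm, was at 10.64 ± 0.32 (SD, n = 6) against 12.51 ± 0.08 (SD, n = 4), 3.63-fold lower. Of 10518 genes tested, 5183 changed with limma at an adjusted p under 0.05, which is 49.3% of those tested. Of these, 2469 were higher and 2714 lower after LPS. At least 2-fold changes were found for 1174 genes, 620 higher and 554 lower. All LPS arrays lay on one side of all PBS arrays for 3960 genes, 37.65% of those tested, where chance gives 0.952%. The median log2 change of all genes tested was -0.01.

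The 10 genes with the highest log2 changes among those with separated arrays encode mainly secreted mediators of inflammation. Saa3, a serum amyloid A acute phase protein, rose by 9.29 on the log2 scale (SE 0.30, adjusted p = 1.39e-09 in limma), or by 8.88 with values under 4 set to 4. The chemokine genes Ccl2 and Cxcl2 were at least 268-fold and at least 254.5-fold higher, and Cxcl5 at least 64.2-fold. Cxcl1 rose by 6.95 from a PBS level of 7.15. Its other 2 probe sets rose by 7.46 and were at least 48.4-fold higher. Adamts4, a matrix protease, was at least 118-fold higher, the cytokine gene Il6 at least 63.1-fold, the protease inhibitor gene Serpina3n at least 74.0-fold and the formyl peptide receptor gene Fpr2 at least 41.4-fold. A fold is given as a lower bound where every array of the dimmer group was at or under a log2 value of 4, since values there carry little signal over background; 108 of the higher genes had all PBS arrays in that range and 42 of the lower genes all LPS arrays.

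Among the 10 lowest log2 changes of genes with separated arrays was that of Pvalb, which encodes the calcium-binding protein parvalbumin of the distal convoluted tubule. Pvalb lay between 2.17 and 2.55 on 5 of 6 LPS arrays, where values carry little signal over background, and at 5.18 on LPS replicate 4. With values under 4 set to 4 it fell by 4.59 (adjusted p = 5.32e-07 in limma). F8, which encodes coagulation factor VIII, fell by 4.10, or by 3.87 with such values set to 4. Ltbp4, which encodes a binding protein of latent TGF-beta, fell by 3.85. Cpne4 was at least 5.56-fold lower. Ces2e and Akr1c21 fell by 4.18 and 4.07, or by 4.11 and 3.67 with such values set to 4. Snx31 fell by 3.67 and 2210409E12Rik by 4.55. Gatm and Miox, enzymes of the proximal tubule, fell by 3.69 and 3.68.

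**Figure D1:**
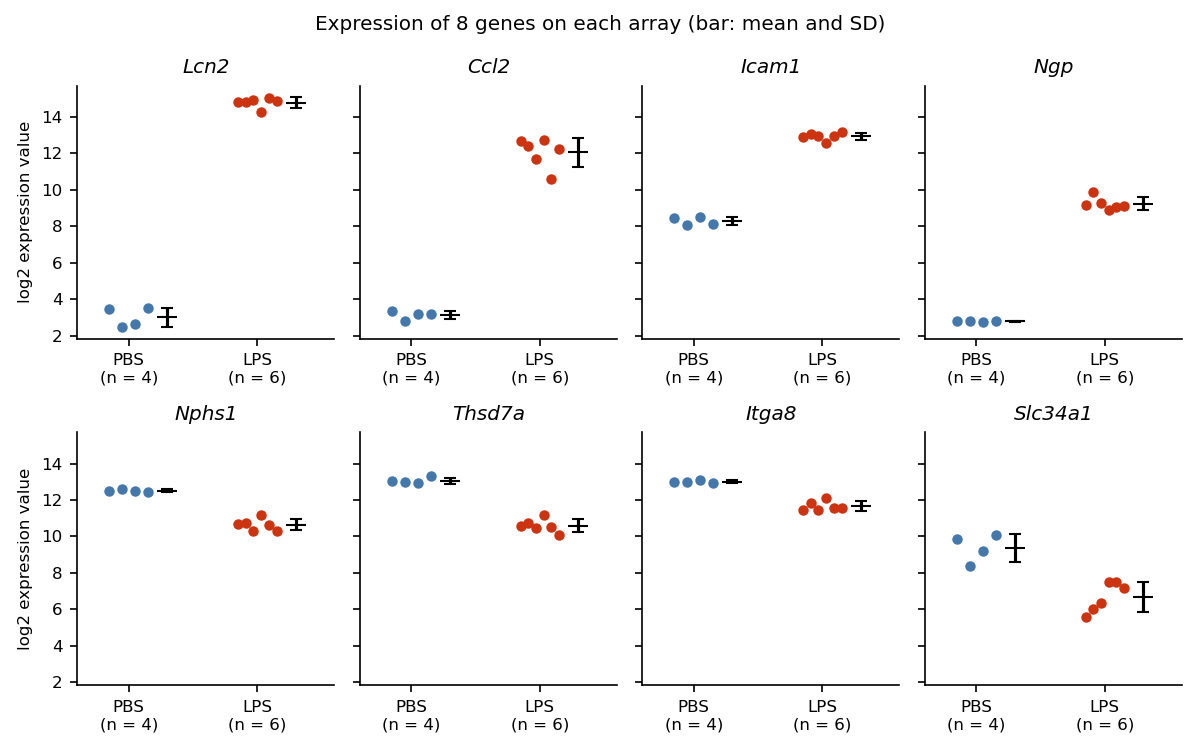
Log2 expression values (vertical axis) of 8 genes on each of the 4 PBS and 6 LPS arrays (points), with the group mean and SD (bar). Icam1 lay between 8.07 and 8.50 on the PBS arrays and between 12.58 and 13.16 on the LPS arrays, and Nphs1 between 12.42 and 12.60 and between 10.31 and 11.17.

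Genes of the endotoxin receptor pathway and the acute phase rose together. Of 19 acute phase entries 13 passed the filter on dim probe sets. Members dim on all PBS arrays, such as Lcn2, passed only through LPS arrays. All 13 measured genes rose (13 also when adjusted over the list alone), with a median log2 change of 4.61, or 3.51 with values under 4 set to 4 (camera adjusted p = 8.68e-11, preset correlation 0.01). Besides Lcn2 and Saa3, the ceruloplasmin gene Cp rose by 4.79, and 7 of its 8 probe sets by 2.605 to 5.82, the other being at least 3.73-fold higher. Of 20 measured genes of Toll-like receptor 4 and NF-kappaB signalling, 17 rose, 1 fell and 2 did not pass the test (17 and 1 adjusted over the list alone), with a median of 1.67 (camera adjusted p = 8.68e-11). Tnfaip3, an inhibitor of NF-kappaB signalling, rose by 4.02, the endotoxin co-receptor gene Cd14 by 3.44, the inhibitor gene Nfkbia by 1.51 and Tlr4 itself by 0.76, while Irak1 fell by 0.47, with another probe set falling by 0.61 and 2 more at -0.15 and -0.05 that did not pass. These were the 2 lists of 33 tested whose calls held with an estimated correlation between genes (adjusted p = 0.0354 for both). For the other lists past the threshold the p with an estimated correlation stands beside the count.

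Most measured chemokines, cytokines and adhesion molecules were higher, on arrays where 7 of 9 neutrophil and 9 of 12 monocyte and macrophage markers were higher too. Of 21 chemokine entries 14 were measured, and those dim on all PBS arrays, such as Ccl2, passed the filter only through LPS arrays. Of these 14 genes 11 rose and none fell (13 and 0 adjusted over the list alone), with a median of 3.61, or 3.22 with values under 4 set to 4 (camera adjusted p = 4.17e-08, adjusted p = 0.0745 with an estimated correlation). Cx3cl1 was at -0.13. Among 16 cytokine and receptor genes 12 rose and 2 fell, both also when adjusted over the list alone, with a median of 1.10, or 0.83 with values under 4 set to 4 (camera adjusted p = 1.15e-04, adjusted p = 0.12 with an estimated correlation). The decoy receptor gene Il1r2 was at least 14.7-fold higher and Csf1, the macrophage growth factor, rose by 1.69, while the TGF-beta receptor gene Tgfbr2 fell by 0.82. Of 9 leukocyte adhesion genes 7 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 1.83 (camera adjusted p = 0.00239, adjusted p = 0.0971 with an estimated correlation). Icam1 was 25.1-fold higher, E-selectin (Sele) rose by 5.19, or by 4.79 with values under 4 set to 4, P-selectin (Selp) was at least 12.8-fold higher, Vcam1 rose by 1.83 and Icam2 fell by 0.80.

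Interferon-stimulated genes and the antigen presentation machinery of class I were higher, and genes of class II were lower. Of 26 measured interferon-stimulated genes 23 rose and none fell, the same counts adjusted over the list alone, with a median of 1.61 (camera adjusted p = 2.26e-13, adjusted p = 0.0745 with an estimated correlation). The transcription factor gene Irf7 rose by 3.64, Ifit3 by 2.30 and Oasl2 by 1.86. All 11 genes of MHC class I and the immunoproteasome rose (11 adjusted over the list alone), with a median of 1.36 (camera adjusted p = 1.01e-08, adjusted p = 0.133 with an estimated correlation); the immunoproteasome subunit gene Psmb8 was 5.27-fold higher, with another probe set rising by 1.21, and Psmb10 rose by 1.42. Of 5 MHC class II genes 4 fell (4 adjusted over the list alone), with a median of -1.57 (camera adjusted p = 0.0353, adjusted p = 0.459 with an estimated correlation). The invariant chain gene Cd74 fell by 1.76, H2-Aa by 1.82 and H2-Eb1 by 1.57, and H2-DMa was at 0.00. On the same arrays the B cell genes Cd79a, Cd79b and Ms4a1 were lower. Of 12 measured monocyte and macrophage markers 9 were higher and Mrc1 was lower. The class II list no longer passed without PBS replicate 1 (camera adjusted p = 0.0727), without LPS replicate 4 (0.0531) or with array weights (0.0577). Its lowest camera adjusted p over all alternatives was 0.003, without a filter on dim probe sets. The median there was unaltered at -1.57, so members kept by the filter were evidently compared with all genes, dim ones included.

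Markers of blood cells moved with the treatment. Of 9 neutrophil markers 7 rose (8 adjusted over the list alone), with a median of 1.41, or 1.30 with values under 4 set to 4 (camera adjusted p = 5.50e-05, adjusted p = 0.204 with an estimated correlation). The granule protein gene Ngp was at least 37.7-fold higher, S100a8 rose by 5.26 and S100a9 by 4.61. Of 12 monocyte and macrophage markers 9 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 2.12, or 2.09 with values under 4 set to 4 (camera adjusted p = 1.28e-04, adjusted p = 0.266 with an estimated correlation). The complement genes C1qa and C1qc, made mainly by macrophages, were at least 12.3-fold and at least 6.39-fold higher and Clec4d at least 7.08-fold, while Mrc1, the mannose receptor gene, fell by 2.55. Mrc1 lay between 10.3 and 10.6 on the PBS arrays, where C1qa, C1qc and Clec4d were all at or under 4. The cells that gave the Mrc1 signal there are therefore uncertain. Of 6 lymphocyte markers 3 fell and 1 rose (3 and 1 adjusted over the list alone) without a call for the list (median -1.16, or -0.42 with values under 4 set to 4; camera adjusted p = 0.147). Those that fell are the B cell genes Cd79b, at least 2.94-fold lower, Ms4a1, at least 3.38-fold lower, and Cd79a, at least 1.51-fold lower. The cytotoxic granule gene Gzma rose by 2.20. Of 4 platelet markers 3 rose and 1 fell (3 and 1 adjusted over the list alone; median 1.78, or 1.67 with values under 4 set to 4; camera adjusted p = 0.0829). Itgb3, the integrin beta 3 gene, was at least 33.2-fold higher, and another of its probe sets at least 1.79-fold. Pf4 rose by 2.54, or by 2.44 with values under 4 set to 4, while Gp1bb fell by 0.79. The 1 erythroid gene measured, Alas2, was at least 2.19-fold lower, and no set test was run on it.

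**Figure D2:**
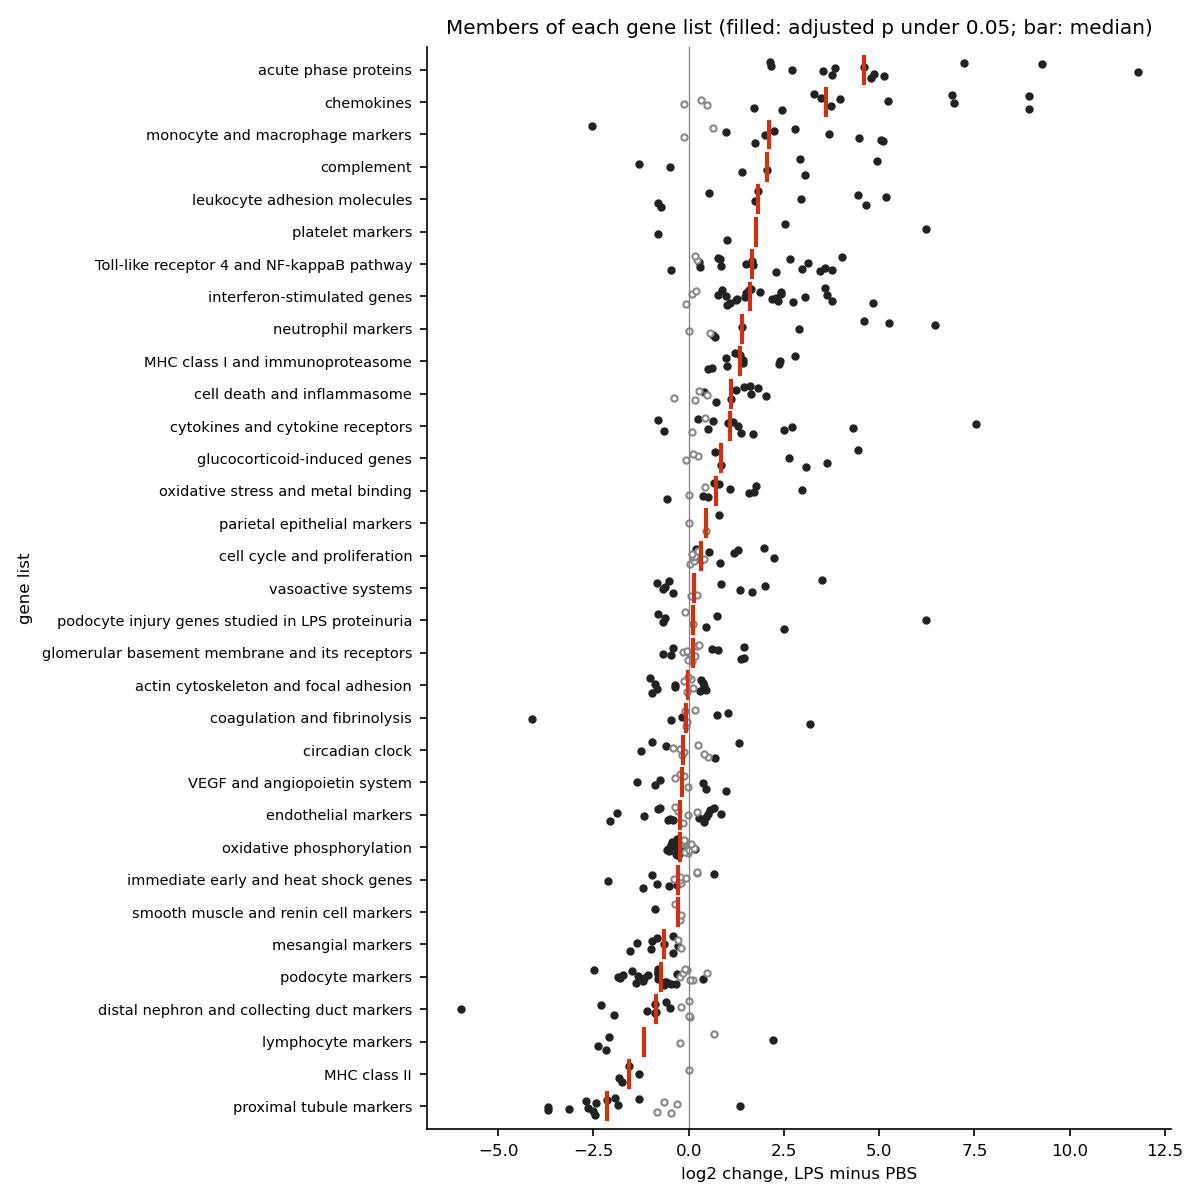
Log2 change, LPS minus PBS (horizontal axis), of each measured member (points, filled where the adjusted p was under 0.05) of the 33 gene lists with at least 3 measured members, with the median of the list (bar). Medians ran from -2.14 for proximal tubule markers to 4.61 for acute phase proteins.

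Podocyte markers were lower as a group. Of 30 measured, 22 fell, 1 rose and 7 did not pass the test (22 and 1 adjusted over the list alone), with a median log2 change of -0.73 (camera adjusted p = 1.94e-07, adjusted p = 0.236 with an estimated correlation). Thsd7a, the gene of a podocyte membrane protein, fell by 2.47 (SE 0.16, adjusted p = 3.40e-07 in limma), Nphs1 by 1.86 (SE 0.14) and Mapt, the tau gene, by 1.81. Synpo, the gene of the actin-associated protein synaptopodin, fell by 0.82 and the transcription factor gene Wt1 by 0.80, each lower on 6 of 6 LPS arrays than on any PBS array. Podxl, the podocalyxin gene and among the brightest on the arrays, fell by 0.31, and its fall after quantile normalization did not pass (log2 change -0.16, adjusted p = 0.0882; over all alternatives between 3.53e-04 and 0.0882). A dimmer probe set of Podxl fell by 1.02 (adjusted p = 0.00118 in limma over all probe sets). Kirrel was higher by 0.37 with an adjusted p of 0.0493, which lay between 0.0308 and 0.123 over all alternatives, and it lost its call without any one of PBS replicates 1, 3 and 4 or LPS replicates 1, 2 and 4, with an adjusted p between 0.0505 and 0.123. The call for Kirrel was also lost without a filter on dim probe sets (adjusted p = 0.0886), with the mean of probe sets (0.051) and with eBayes without trend (0.0587). Without LPS replicate 4, 22 podocyte markers fell and 0 rose. Markers of tubule segments were lower and those of neutrophils and macrophages higher on the same arrays.

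Of 11 mesangial markers 9 fell and none rose (10 and 0 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 4.53e-04, adjusted p = 0.233 with an estimated correlation). Art3 fell by 1.54, the integrin alpha 8 gene Itga8 by 1.35 and Nt5e by 0.97. The 20 endothelial markers went both ways, 7 rising and 8 falling (7 and 8 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.346). Ehd3, a gene of the glomerular endothelium, was 4.18-fold lower, Ptprb, the vascular endothelial phosphatase gene, 3.69-fold lower and Igfbp5 2.24-fold lower, while Sox18 rose by 0.67. A dimmer probe set of Igfbp5 fell by 1.88 on the log2 scale and one of Ptprb by 1.49. Kdr, the VEGF receptor 2 gene, was at -0.02 (SE 0.15), a change within the spread of the arrays. Of 4 smooth muscle and renin cell markers, Smtn fell by 0.89 and 3 did not pass (1 adjusted over the list alone; median -0.29; camera adjusted p = 0.252); without LPS replicate 4, in an alternative chosen after the data were seen, 3 fell. Of 3 parietal epithelial markers Wnt4 was at least 1.29-fold higher with an adjusted p of 0.0259, and the others did not pass (2 higher adjusted over the list alone; median 0.47, or 0.40 with values under 4 set to 4; camera adjusted p = 0.372). The call for Wnt4 was lost with values under 4 set to 4 (adjusted p = 0.15), with the replicate number as a block (adjusted p = 0.0509), without PBS replicate 1 (adjusted p = 0.0876) and without PBS replicate 4 (adjusted p = 0.0542), and the lowest adjusted p over all alternatives was 0.0119.

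Tubule markers, of cells that lie outside the glomerulus, were lower. Of 17 proximal tubule markers 12 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -2.14, or -1.70 with values under 4 set to 4 (camera adjusted p = 4.53e-04, adjusted p = 0.459 with an estimated correlation). The megalin gene Lrp2 fell by 2.65 and another of its probe sets by 1.64. With values under 4 set to 4, Lrp2 fell by 2.61. The phosphate transporter gene Slc34a1 fell by 2.71. Pck1, a gluconeogenic enzyme gene, rose by 1.35 and lost its call without PBS replicate 2 (adjusted p = 0.0575, where the lowest over all alternatives was 0.00575). Of 13 distal nephron and collecting duct markers 9 fell and none rose (9 and 0 adjusted over the list alone), with a median of -0.85 (camera adjusted p = 0.0032, adjusted p = 0.367 with an estimated correlation); the cotransporter gene Slc12a1 fell by 2.31 and Hsd11b2 by 0.85. Umod, the uromodulin gene of the same segment as Slc12a1, chosen here after its values were seen, was at 13.66 ± 0.33 (SD, n = 6) after LPS and 13.64 ± 0.25 (SD, n = 4) after PBS, a difference within the spread of the arrays.

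**Figure D3:**
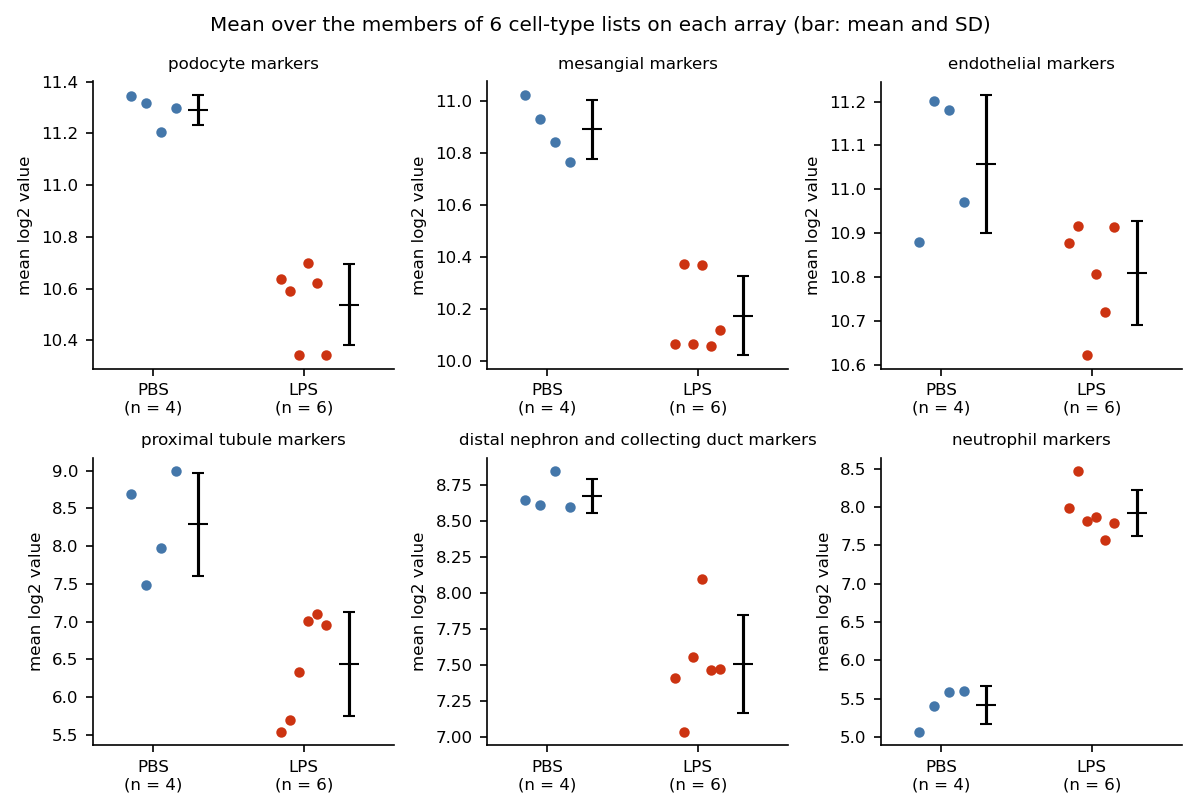
Mean log2 value (vertical axis) over the measured members of 6 cell-type lists on each of the 4 PBS and 6 LPS arrays (points), with the group mean and SD (bar); the vertical axes differ and do not start at 0. The podocyte mean lay between 11.21 and 11.34 on the PBS arrays and between 10.34 and 10.70 on the LPS arrays, and the endothelial means of both groups overlapped.

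Genes of the basement membrane and of the cytoskeleton moved in both directions. Of 17 genes of the glomerular basement membrane and its receptors 5 rose and 3 fell (5 and 3 adjusted over the list alone; median 0.12; camera adjusted p = 0.209). The collagen IV genes Col4a1 and Col4a2 rose by 1.37 and 1.47 and the laminin gene Lamc1 by 1.45, with a dim second probe set of Lamc1 at 0.35 with values under 4 set to 4, while the dystroglycan gene Dag1 fell by 0.67. Among 16 genes of the actin cytoskeleton and focal adhesions 5 rose and 6 fell (5 and 7 adjusted over the list alone; median -0.03; camera adjusted p = 0.485). Vcl, the vinculin gene, was 2.01-fold lower, Arhgap24 fell by 0.95 and Myh9 by 0.35, while the moesin gene Msn rose by 0.41. Another probe set of Msn was at 0.31 and did not pass, and the 5 probe sets of Myh9 lay between -0.79 and -0.18. Of 9 genes studied in endotoxin proteinuria as podocyte injury genes 4 rose and 3 fell (4 and 3 adjusted over the list alone; median 0.13; camera adjusted p = 0.515). Besides Itgb3, the urokinase receptor gene Plaur rose by 0.74, the cathepsin L gene Ctsl by 0.45 and Angptl4 by 2.50. The groups overlapped for Angptl4, which lay between 6.58 and 8.95 on the PBS arrays and at 8.95 on LPS replicate 4. Itgb3 is also counted among the platelet markers, and the cells in which these genes rose were not determined. Of 10 genes of the VEGF and angiopoietin system 3 rose and 3 fell (3 and 3 adjusted over the list alone; median -0.17; camera adjusted p = 0.659): Angpt2 rose by 0.99, Nrp1 fell by 0.87 and Tek by 0.74. Pgf fell by 1.36, or by 1.35 with values under 4 set to 4, and Vegfa was at -0.12 (SE 0.12), within the spread of the arrays.

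Genes of cell death, stress and complement rose for the most part. Of 13 cell death and inflammasome genes 9 rose and none fell (12 and 1 adjusted over the list alone), with a median of 1.12 (camera adjusted p = 2.76e-05, adjusted p = 0.0745 with an estimated correlation); Bid rose by 2.04, Mlkl, the effector gene of necroptosis, by 1.83 and the gasdermin D gene Gsdmd by 1.25. Of 7 complement genes 5 rose and 2 fell (5 and 2 adjusted over the list alone), with a median of 2.06, or 1.82 with values under 4 set to 4 (camera adjusted p = 0.00383, adjusted p = 0.0745 with an estimated correlation). Cfb, the factor B gene, was 30.9-fold higher, Serping1 rose by 2.92 and C1ra by 3.04, while Cd59a, which encodes an inhibitor of the membrane attack complex, fell by 1.31. Of 12 genes of oxidative stress and metal binding 9 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.72 (camera adjusted p = 0.00148, adjusted p = 0.313 with an estimated correlation); Sod2 rose by 1.77, Hmox1 by 1.59 and the metallothionein gene Mt2 by 2.97, and the catalase gene Cat fell by 0.57. Of the other probe sets of Sod2, 1 rose by 1.56 and 1 was at -0.15 and did not pass. Of 9 genes that glucocorticoids induce 6 rose and none fell (6 and 0 adjusted over the list alone), with a median of 0.86 (camera adjusted p = 0.00239, adjusted p = 0.313 with an estimated correlation); Fkbp5 rose by 3.63, Zbtb16 by 4.45, or by 3.70 with values under 4 set to 4, and Cebpd by 3.08. Of the other probe sets of Zbtb16, 1 was at least 2.81-fold higher and 1 rose by 2.95 with values under 4 set to 4. Of 15 cell cycle genes 8 rose and none fell (8 and 0 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.00649, adjusted p = 0.367 with an estimated correlation), and 5 rose without LPS replicate 4. The cell cycle inhibitor gene Cdkn1a rose by 2.23, Mcm5 by 1.19 and Rrm2 by 1.97, or by 1.85 with values under 4 set to 4. A dim second probe set of Rrm2 was at 0.57 with such values set to 4.

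Of 30 nuclear-encoded genes of oxidative phosphorylation 19 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 4.53e-04, adjusted p = 0.461 with an estimated correlation); Ndufa1 fell by 0.58, Cox6c by 0.51 and Sdha by 0.43. On the same arrays the medians of proximal and distal tubule markers were -2.14 and -0.85. Of 14 immediate early and heat shock genes 6 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.27; camera adjusted p = 0.139); Atf3 fell by 1.20, Jun by 0.96 and Egr1 by 0.84, and Junb rose by 0.67. This list passed without PBS replicate 1 (median -0.34, camera adjusted p = 0.0451). It also passed with no filter on dim probe sets (camera adjusted p = 0.012), where its median was unaltered. There the members kept by the filter were evidently compared with all genes, dim ones included. Of 12 vasoactive genes 5 rose and 5 fell (5 and 5 adjusted over the list alone; median 0.14; camera adjusted p = 0.486); the cyclooxygenase 2 gene Ptgs2 rose by 3.50 and Gch1 by 2.01, while another probe set of Ptgs2 was at least 2.28-fold higher and another of Gch1 was at 0.45 and did not pass. The natriuretic peptide receptor gene Npr1 fell by 0.84. Of 10 coagulation and fibrinolysis genes 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.929), F13a1 rising by 3.18, or by 2.97 with values under 4 set to 4; the median was -0.06 and the mean 0.01, which with the direction of the test differ in sign. Of 12 circadian clock genes 2 rose and 3 fell (2 and 3 adjusted over the list alone; median -0.14; camera adjusted p = 0.929); Bhlhe40 rose by 0.70, and Tef fell by 0.96 and lost its call without PBS replicate 2 (adjusted p = 0.0526, where the lowest over all alternatives was 0.00355). A dim second probe set of Tef was at -0.42 and did not pass, or at -0.30 with values under 4 set to 4.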

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

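The tests of chance, of tubule and podocyte RNA, of the normalization and of LPS replicate 4 were chosen after the results were seen. Among 100 splits of the 10 arrays into groups of 4 and 6, the real one included, only the real split gave as many as 5183 changed genes (1 of 100), and the highest of the others gave 335. For genes changed at least 2-fold the real split gave 1174, the highest other 165, and again 1 of 100 reached the real count, so that chance division of these arrays can be excluded for both counts.

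Most tubule markers fell, and less carried-over tubule RNA in the LPS preparations cannot be told apart from lower transcript levels inside tubule cells. The 17 measured proximal tubule markers varied together from array to array within each group, with a mean pairwise correlation of 0.668, where 10000 random lists of like expression had a 95th percentile of 0.0857, and the 13 distal markers did so with 0.377 against 0.0982. Such variation within groups would follow from varying amounts of tubule RNA or from joint regulation, and does not show that the LPS preparations held less. Of the markers with a PBS mean above 7, 9 of 13 proximal and 7 of 8 distal ones were lower; Pck1 rose by 1.35 and Umod was at 0.01, while Slc12a1 of the same segment fell by 2.31. The call for Pck1 was lost without PBS replicate 2 (adjusted p = 0.0575).

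Podocyte markers fell. A loss of podocyte RNA alone, with the RNA of the other cell types kept, would not lower the mean of the mesangial markers. That mean changed by -0.72, with an SD of 0.15 on the LPS arrays and 0.11 on the PBS arrays (exact two-sided permutation p = 0.00476, n = 6 and 4, the smallest this design can give). Such a loss alone therefore does not account for both falls. The mesangial mean cannot tell what lowered the podocyte markers, since the mesangial markers may have changed separately. Other genes of that expression level did not fall as a group: of 10000 random lists matched on expression 0 had a median as low, the lowest being -0.35. The normalization sets the distributions of the arrays equal, so a shift of all genes at 1 level would hardly show in these values. The random genes were also drawn without regard to the correlation within the podocyte list. This comparison therefore cannot decide about a shift from the normalization. Even dilution of podocyte RNA by RNA of other cells, or an even loss of it, would lower podocyte markers by a like amount. That holds only if no other cells gave signal for the markers and all probe sets responded alike. Of 30 measured, 22 fell, 1 rose and 7 did not pass. Their changes ran from -2.47 to 0.47, with Nphs1 at -1.86 (SE 0.14) and Synpo at -0.82 (SE 0.08). Probe sets of 1 gene also differed, as for Podxl (-0.31 and -1.02). The unequal changes therefore cannot decide about dilution or an even loss. Dilution of podocyte and mesangial RNA, a loss of podocyte RNA and lower transcript levels in the cells stay open for the podocyte markers.

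LPS replicate 4 showed weaker changes than the other LPS arrays. Its value on the first principal component was 20.67, where the next LPS array had 32.61, and the slope of its changes against the mean of the other LPS arrays was 0.818, against 0.969 to 1.06. Mixed-in RNA of the PBS kind and a weaker response cannot be told apart: the share of PBS-like RNA that would account for its values was 0.142 from genes that fell and 0.282 from genes that rose, a difference of 0.14 that is close to the 0.132 of another LPS array. No other technical explanation was tested for LPS replicate 4. It was not the only array to stand apart. LPS replicate 5 had the lowest array weight of the LPS arrays (0.412, against 0.848 for LPS replicate 4) and lay at 26.62 on the second principal component. Leaving out LPS replicate 5 gave 5393 changed genes, the most of any single removal.

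Single arrays lying far from the rest of their group were found in 27 of 354 groups tested, and chance alone gives about 5%. LPS replicate 4 lay apart for Lcn2 (14.25), Adamts4 (9.46), Angptl4 (8.95) and Ptgs2 (6.78) as the lowest LPS array and for Pvalb (5.18), Slc12a1 (9.97) and the mean of smooth muscle and renin cell markers (8.97) as the highest. LPS replicate 5 was lowest for Csf1 (11.05), Mlkl (8.54) and the mean of chemokines (9.07). LPS replicate 2 was highest for Ngp (9.91) and Hey1 (2.63), and LPS replicate 6 for H2-DMa (5.49) and Psmb10 (11.21). PBS replicate 1 was lowest for Ces2e (7.51) and Mmp7 (1.97) and highest for Ctsl (13.66), Ms4a1 (6.40) and Rrm2 (5.47). PBS replicate 2 was lowest for Sqle (5.03) and highest for Zc3h12a (4.70). PBS replicate 3 was lowest for Fpr2 (2.36), Mapt (13.64) and Vegfa (11.53) and highest for the mean of glucocorticoid-induced genes (9.36). PBS replicate 4 was highest for Snx31 (10.47).

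Probe sets without a single gene symbol, which the gene comparison left out, also differed between the groups: of 1881 past the filter 797 changed with limma, 392 higher and 405 lower after LPS.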

How the results depend on the processing

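The counts of list members without LPS replicate 4 were chosen after the data were seen, and the other alternatives before. The number of changed genes lay between 4614 and 5585 over alternatives with 1 value per gene at the same threshold. It was 3842 at an adjusted p under 0.01, and leaving out single arrays gave 4657 to 5393. With every probe set on its own, 5784 genes had at least 1 changed probe set, a measure that gives genes with several probe sets more chances. At least 2-fold changed genes numbered 960 to 1245 with 1 value per gene, and 1391 genes had at least 1 such probe set. With quantile normalization 5112 of the changed genes were again called, all in the same direction, and with the mean of a gene's probe sets 4668, of which 4637 in the same direction. With the replicate number as a block (replicate block) 4614 genes changed, 4365 of them shared; array correlations gave no sign that equal numbers pair mice, so that fit is given only as an alternative. Without a filter on dim probe sets the lists of immediate early and heat shock genes (median -0.27) and of lymphocyte markers (-1.16) passed. Both medians equalled those with the filter, so list members dropped by the filter evidently stayed out. Members kept by the filter were thus compared with all genes, dim ones included, which is no test of whole lists without a filter. The median of immediate early and heat shock genes ranged from -0.34 to -0.21 when single arrays were left out. MHC class II, at -1.65 with array weights, ranged from -1.80 to -1.36. The median of vasoactive genes was -0.10 with a stricter filter. That of actin cytoskeleton genes was 0.072 with the mean of probe sets and 0.0032 with the replicate block, and ranged from -0.071 to 0.016 when single arrays were left out. With an estimated correlation 18 lists no longer passed, at unaltered medians: 1.36 for MHC class I, -1.57 for MHC class II, 0.32 for cell cycle, 1.12 for cell death, 3.61 for chemokines, 2.06 for complement, 1.10 for cytokines, -0.85 for distal nephron, 0.86 for glucocorticoid-induced, 1.61 for interferon-stimulated, 1.83 for adhesion, -0.64 for mesangial, 2.12 for monocyte, 1.41 for neutrophil, -0.23 for oxidative phosphorylation, 0.72 for oxidative stress, -0.73 for podocyte and -2.14 for proximal tubule genes. That test widens the variance of a list by the correlation between its genes. With fry, which asks only whether genes move one way, the lists of actin cytoskeleton (-0.030), endothelial (-0.22), basement membrane (0.12), lymphocyte (-1.16), platelet (1.78), podocyte injury (0.13), smooth muscle (-0.29) and vasoactive genes (0.14) passed. Among genes without a call, Kdr was at 0.033 with array weights and between -0.18 and 0.082 when single arrays were left out, and H2-DMa at -0.060 with the replicate block and between -0.25 and 0.22. Umod was at -0.023 with quantile normalization, -0.099 with array weights and -0.046 with the replicate block, and between -0.11 and 0.11 when single arrays were left out. Apart from the tests with other assumptions, the cause was not tested. Signal over background limits the dim genes: folds are lower bounds where every array of a group was at or under 4, and where only some arrays were, the size of the change stays uncertain.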

Other observations

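The 11 lists here were written, and all tests on them chosen, after the main results were seen, so they describe these arrays and are no independent evidence; the genes named from them were also chosen after their values were seen. All 31 measured members of a list of subunits of the proteasome, the complex that degrades ubiquitin-tagged proteins, were higher after LPS (31 adjusted over the list alone). These subunits rose by a median of 0.63 on the log2 scale and by 0.34 to 0.95 each (camera adjusted p = 2.42e-14, adjusted p = 0.144 with an estimated correlation). The hypothesis that any genes of their expression level would show this was tested with random lists: 0 of 10000 matched lists held as many higher members, their median was 8 and the most was 18. Those lists drew genes independently, while the subunits had an estimated correlation of 0.336. The 0 of 10000 therefore overstates the evidence for the list. Of 16 genes of the amino acid response and one-carbon metabolism 11 rose and none fell (12 and 0 adjusted over the list alone), with a median of 1.29 (camera adjusted p = 5.44e-06, adjusted p = 0.187 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme gene, rose by 5.65, or by 5.41 with values under 4 set to 4, Asns, the asparagine synthetase gene, by 4.06 and Phgdh, the gene of the first enzyme of serine synthesis, by 3.51. Other probe sets of Phgdh rose by 2.70 and 3.68, and a dim one was at least 1.83-fold higher. Another probe set of Mthfd2 rose by 4.80, or by 4.29 with values under 4 set to 4. Of 13 genes of cholesterol synthesis 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 2.40e-05, adjusted p = 0.252 with an estimated correlation); the squalene epoxidase gene Sqle rose by 2.64 and Dhcr7 fell by 1.28.

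Of 10 matrix proteases and inhibitors 7 rose and 2 fell (7 and 3 adjusted over the list alone; median 0.53; camera adjusted p = 0.0417, adjusted p = 0.16 with an estimated correlation); Mmp7 was at least 14.2-fold higher and Timp1 at least 8.48-fold. Of 11 negative regulators of cytokine signalling 6 rose (6 adjusted over the list alone; median 0.30; camera adjusted p = 0.0109, adjusted p = 0.144 with an estimated correlation), among them Zc3h12a, by 3.03. Of 28 ribosomal protein genes 14 rose and 1 fell (14 and 1 adjusted over the list alone), by a median of 0.14 (camera adjusted p = 0.0417, adjusted p = 0.667 with an estimated correlation). Of 12 Notch pathway genes 5 fell and 1 rose (5 and 1 adjusted over the list alone; median -0.21; camera adjusted p = 0.0853), where the target gene Hey1 was at least 2.82-fold lower and the ligand gene Dll4 fell by 2.39, with another probe set falling by 1.45; without LPS replicate 4, 2 rose. The lists of endoplasmic reticulum stress (5 of 14 higher, 3 lower; camera adjusted p = 0.537), glycolysis (5 of 11 higher, 0 lower, or 1 lower without LPS replicate 4; camera adjusted p = 0.147), fatty acid oxidation and peroxisome (6 of 15 higher, 4 lower; camera adjusted p = 0.66) and fibrillar collagens and matrix proteins (4 of 10 higher, 4 lower; camera adjusted p = 0.75) did not pass; in the last, Dcn, the decorin gene, was at least 19.9-fold higher and the periostin gene Postn fell by 2.29.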
